A study of Bos indicus x Bos taurus and Bos indicus with 5 samples.

How the data were processed

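The study asked which genes are read from a single parental allele in bovine conceptuses at about day 105 of gestation. The conceptuses were F1 hybrids, and the labels name a Bos taurus indicus (Nelore) sire. A read that carries the indicus base was therefore taken as paternal and a read that carries the taurus base as maternal. No dam DNA is among the samples, so whether a dam carried the indicus base at some positions could not be checked here. The series holds 5 samples, which are 4 placenta RNA libraries and 1 library of DNA from the sire's semen. RNA was read as poly-A-selected, fragmented and randomly primed TruSeq cDNA, per the labels' protocols, which state no strand marking. Overlapping and antisense transcripts therefore cannot be told apart.

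The data analysed were 1 deposited table of 56 rows, each a gene or transcript that its title describes as read from 1 allele. For brain, kidney, liver, skeletal muscle and placenta the authors deposited allele-specific read counts, not normalized, for the taurus and the indicus allele, with the percent of reads on the allele they call repressed. No column names a conceptus, so each value was taken as the authors' pool over the libraries of a tissue. The brain, kidney, liver and muscle libraries are not among the 5 samples here, and their pools are used only as the table gives them. How positions were combined per gene, and by which criteria the table's genes were called monoallelic, is not given in the sources used here. The submitters' processing notes name the build UMD3.1, a taurus assembly, and CASAVA, SAMtools, Bowtie2 2.2.3, HISAT2 2.0.0, BWA 0.7.7, Cufflinks 2.2.1, HTSeq 0.5.4 and edgeR 3.8.6, without saying what each was used for. The cells ND and LE, which the table does not define, were treated as no value.

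The deposited percent values were checked against the counts. In 218 of 219 cells the percent was within 0.1 points of the share of 1 of the alleles. For SNRPN in placenta the deposited percent is 0, while its counts give 0.94%. The indicus count of NAP1L5 in skeletal muscle is 41.5, which is not a whole number, and that cell was left out. MEG3 has the same pair of counts, 39045 and 674, in brain and in kidney, so at least 1 of these cells is probably a copy. The row named LOC100848941 carries the gene ID 100848981, and the name was used as given.

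The maternal share was computed as taurus reads over the sum of taurus and indicus reads, for genes with at least 10 such reads in a tissue, with an exact 95% Clopper-Pearson interval. Each share was set against 50% with a two-sided exact binomial test on reads, with Benjamini-Hochberg adjustment over the genes of a tissue and a threshold of 0.05. A gene was counted as read from 1 allele at a share of at least 90%, as preferentially read from 1 allele from 70%, and otherwise as read from both alleles. Differences between tissue pools were tested with the chi-square statistic of the tissue by allele table against 100000 random tables with the same margins (a permutation test). Placenta was set against each other tissue with Fisher's exact test, two-sided, and a Newcombe 95% interval of the difference, adjusted over all genes and the 4 tissues together. These tests compare reads of pools. With 1 pool per tissue they carry no spread between conceptuses, and reads without molecular identifiers are not independent molecules, so intervals, limits and p-values cover counting error only. A read count of 0 was taken to allow up to 3 counts. This gives a lower limit than the two-sided exact interval, such as 9.38% against 10.9% for the paternal share of LOC104974975 in placenta.

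Before the data were examined, the sample groups, the 90% and 70% limits, the minimum of 10 reads, the gene lists and the rule for named genes were fixed. The rule took the measured members of a list of 29 paternally expressed and a list of 37 maternally expressed genes, plus, in each direction, the 10 other genes with the largest allele ratio in placenta (0.5 reads added to each count) among those past the threshold. Its further condition, the same direction in every conceptus, could not be applied to pooled counts. The 90% limit had been meant for every conceptus and was applied to the pool. The table holds 16 and 9 genes of the lists. Of 9 endometrium, 9 trophoblast and 5 blood marker genes fixed at the same time, 0, 0 and 0 are in the table. The replicated quasi-likelihood test, the rotation test of the lists and the test of spread between conceptuses that had been planned need counts per conceptus. They were not run, and the tests above on pooled reads took their place. The tissue comparisons, and the 20-point limit used to describe them, were chosen after the table had been seen, as were the genes named there that the rule does not cover.

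The 31 symbols found in a gene table of the assembly UOA_Brahman_1 were used only to tell which genes neighbour each other, because the build differs, and 0 of the 31 lie on X. Coordinates on UMD3.1 were not used here. Alternatives tried were other minimum read numbers, other share limits, another null share, counts divided by 2 or by 10 and leaving out tissues or entries. On simulated reads at the placenta depths, run on 1000 simulated genes, the allele test called 99% of genes with a true share of 95%, 89% of genes with a share of 30% and 1.25% of genes with a share of 50%. The tissue test, on 300 simulated genes and with fewer random tables, called 95% of genes with 1 tissue at 50% against 80% in the others, and 2.5% of genes without a difference. The simulated reads were independent draws at fixed shares, so these rates cover counting error only and no spread between conceptuses. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.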

Results

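Allele-specific transcription was measured by RNA sequencing in day 105 hybrid bovine conceptuses, in which sequence differences between the taurus dams and the indicus sire were taken to mark the parental origin of a read. The placenta group comprised 4 libraries, all labelled as controls, and 1 DNA library of sire semen carries no expression values and entered no comparison. The placenta pool held 291276 allele-specific reads over 43 of the 56 listed genes, with a median of 450 and a range of 11 to 138964 reads per gene. The 4 other tissues came as pools of 90911 reads in brain, 263853 in kidney, 152693 in liver and 362374 in skeletal muscle. The brain and kidney pools each include 39719 MEG3 reads from the same pair of counts, of which at least 1 cell is probably a copy. H19 and MEG3 alone held 138964 and 49546 of the placenta reads. All values are the authors' pooled counts without replicates, so brackets give 95% counting intervals, and no value carries an error between conceptuses.

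The first comparison asked which parental allele each gene was read from in placenta. Of 43 genes, 42 departed from an equal share of the alleles, 19 with the maternal and 23 with the paternal allele higher (exact binomial test on reads, Benjamini-Hochberg adjusted p under 0.05). At least 90% of reads came from a single allele in 30 genes, from the maternal allele in 12 and from the paternal allele in 18. A further 6 genes had a preference of 70% or more, 4 maternal and 2 paternal, and 7 were read from both alleles. The table holds genes listed as monoallelic, so these counts describe the list and not the transcriptome.

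Genes known for paternal expression were read almost entirely from the indicus allele in placenta. Of 12 measured members of that list, 11 passed the test, all with the paternal allele higher, and the count was also 11 when adjusted over the list alone. IGF2, the fetal growth factor, had 24 maternal among 28509 reads, a maternal share of 0.084% [0.054 to 0.125]. The maternal share was 1.02% [0.62 to 1.59] for PLAGL1, a zinc finger transcription factor, and 0.94% [0.38 to 1.92] for SNRPN, a component of small nuclear ribonucleoproteins, for which the deposited percent is 0. SGCE, epsilon-sarcoglycan, had 1.19% [0.78 to 1.75], and PEG3, a zinc finger protein, had 4.81% [4.44 to 5.20]. BEGAIN had 1 maternal read among 88 and MAGEL2 had 3 among 98. The maternal share reached 6.42% [3.78 to 10.1] for DIRAS3, a Ras-like GTPase, and 8.36% [5.78 to 11.6] for RTL1, a retrotransposon-derived gene with a known antisense transcript that these libraries cannot separate. DLK1, a Notch-ligand-like protein, was covered by 12 reads, 11 of them paternal, with an interval of 0.21 to 38.5% for the maternal share. PEG10, another retrotransposon-derived gene with a known role in placental development, stayed below the 90% limit with a paternal share of 87.7% [86.8 to 88.5]. INPP5F, an inositol polyphosphate phosphatase, was the member that did not pass, with 7 maternal and 4 paternal reads (exact binomial adjusted p = 0.549) and an interval of 30.8 to 89.1% for the maternal share.

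Genes known for maternal expression were read mainly from the taurus allele in placenta. All 9 measured members passed the test with the maternal allele higher, over all genes and adjusted over the list alone, and 7 had a share above 90%. PHLDA2, a pleckstrin homology protein known to restrain placental growth, had a maternal share of 99.8% [99.7 to 99.9] over 13192 reads. CDKN1C, a cyclin-dependent kinase inhibitor that lies near PHLDA2, had 99.7% [99.3 to 99.8] over 2298 reads. The long noncoding RNA H19 had 97.8% [97.8 to 97.9]. The noncoding RNAs of the DLK1 region reached similar levels, with 97.5% [97.3 to 97.6] for MEG3, 97.4% [97.1 to 97.8] for MEG8 and 276 of 277 reads maternal for MEG9. GNAS, the locus of the stimulatory G protein alpha subunit, had 97.4% [94.8 to 99.0] over 274 reads. Its exons overlap those of the paternally read GNASXL, and which transcripts of the locus these reads came from is not given. IGF2R, the receptor that clears IGF2, had a preferential share of 82.7% [81.6 to 83.8]. PPP1R9A, an actin-binding neurabin, had 66.1% [62.7 to 69.3] and fell in the class read from both alleles.

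**Figure D1:**
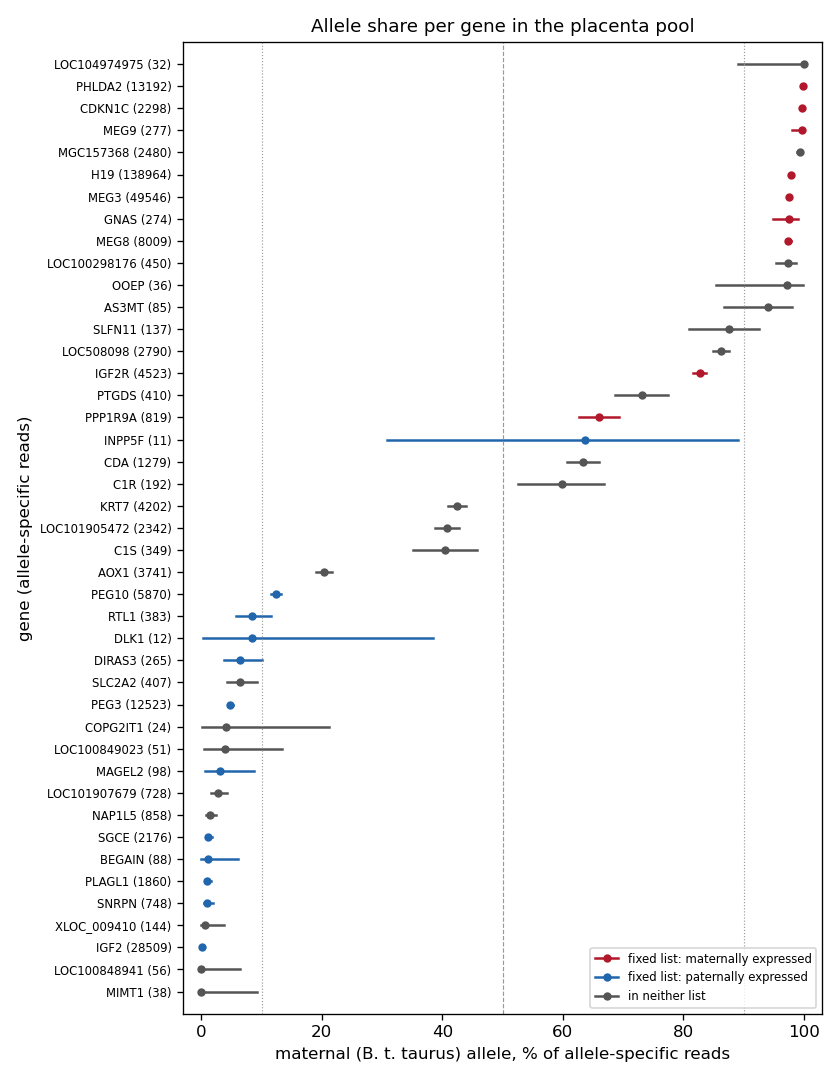
Maternal allele share of each gene in the placenta pool, as a percent of allele-specific reads (x axis), with genes on the y axis and their read number in brackets. Points are shares, bars are 95% Clopper-Pearson intervals, dotted lines mark 10% and 90%, and colours mark the lists. Of 43 genes, 12 lie at or above 90%, 18 lie at or below 10%, and INPP5F has the widest interval, 30.8 to 89.1%.

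The higher allele followed the 2 lists. In placenta the maternal allele was higher in 9 of 9 genes of the maternal list and in 1 of 12 genes of the paternal list, which was INPP5F (Fisher's exact test, two-sided, p = 3.4e-05, adjusted over 5 tissues 3.4e-05). In kidney the maternal list had the maternal allele higher in 9 of 9 genes and the paternal list the paternal allele higher in 13 of 13 (Fisher's exact adjusted p = 1.01e-05). The split was likewise without exception in brain (8 and 11 genes), liver (9 and 10 genes) and skeletal muscle (8 and 12 genes), each with a Fisher's exact adjusted p of 1.65e-05. These counts take the higher allele whether or not the gene passed the allele test. IGF2R in brain, with 320 maternal and 313 paternal reads, and INPP5F in liver did not pass (exact binomial adjusted p = 0.812 and 0.082). The lists come from textbook knowledge, but the table's title presents its genes as found to be monoallelic in these conceptuses, so they are not an independent sample of the lists.

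Among the 22 genes outside the lists, all passed the test in placenta, 10 with the maternal and 12 with the paternal allele higher. Every conceptus had an indicus sire and no reciprocal cross was analysed here, so the maternal allele was always the taurus allele. For these genes a sequence difference between the subspecies therefore cannot be told apart from an effect of parental origin. The maternal group included MGC157368 at 99.3% [98.9 to 99.6] over 2480 reads, LOC100298176 at 97.3% [95.4 to 98.6], and LOC104974975 with 32 of 32 maternal reads, where a count of 0 allows a paternal share of up to 9.38%. AS3MT, the arsenite methyltransferase, had 94.1% [86.8 to 98.1] and OOEP, an oocyte-expressed protein, had 97.2% [85.5 to 99.9] on 36 reads. LOC508098 at 86.3%, SLFN11 at 87.6% and PTGDS, a prostaglandin D synthase, at 73.2% were preferentially maternal. CDA, cytidine deaminase, at 63.3% [60.6 to 66.0], and C1R, a protease of the complement system, at 59.9% [52.6 to 66.9], were read from both alleles.

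The paternal group outside the lists included the noncoding RNA MIMT1 with 38 of 38 paternal reads (a maternal share of up to 7.89% is allowed) and LOC100848941 with 56 of 56 (up to 5.36%), a row that carries the gene ID 100848981, so that which gene it measures is uncertain. The paternal share was 98.6% [97.6 to 99.3] for NAP1L5, a nucleosome assembly protein, 99.3% for XLOC_009410 on 144 reads and 97.3% [95.8 to 98.3] for LOC101907679. LOC100849023 had 49 paternal among 51 reads and COPG2IT1 had 23 among 24. SLC2A2, a glucose transporter, had 93.6% [90.8 to 95.8] paternal reads. AOX1, an aldehyde oxidase, was preferentially paternal at 79.7%, and the complement protease C1S was read from both alleles at 59.6% [54.2 to 64.8] paternal. SLC2A2, SLFN11, PTGDS and ALDH8A1 are marked in the table as lacking verification by Sanger sequencing. The small preferences of C1R and C1S no longer passed the exact binomial test with counts divided by 10, and that of C1R already with counts divided by 2.

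The second comparison asked whether the allele read was shared between tissues. Of 48 genes measured in at least 2 tissues, 20 had 90% or more of reads from the same allele in every tissue measured, 8 maternal and 12 paternal. The maternal set included H19, MEG3, MEG8, MEG9, GNAS and PON3, a paraoxonase, and the paternal set included PLAGL1, SNRPN, MAGEL2, DIRAS3, NAP1L5, MIMT1 and LOC100848941. Some of these were not measured in every tissue, such as PON3 and NAP1L5 in 4 and DIRAS3 in 3. Of 31 genes measured in all 5 tissues, 14 did so, 6 maternal and 8 paternal. SNRPN had 0 maternal among 5958 reads in brain, which allows up to 0.0504%. The MEG3 counts of brain and kidney are the same pair, so for that gene only 4 distinct pairs of counts stand behind the statement. Of the 20, 10 lie outside the lists, and for these a sequence difference between the subspecies cannot be told apart from an effect of parental origin. Membership in the set of 20 rests on point shares. For DLK1, a member with 12 placenta reads, the interval of the paternal share there is 61.5 to 99.8%. PEG3 missed the set through skeletal muscle alone, where its paternal share was 89.99%.

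Allele shares differed between tissue pools by more than read sampling in 38 of 48 genes (permutation test, adjusted p under 0.05), and the span between the highest and lowest tissue was 20 points or more in 19 of them. The span was 5 to 20 points in 8 and under 5 points in 11. With counts divided by 10 the test called 24 genes. The 10 genes that did not pass included PEG10, whose maternal share lay between 11.7% in liver and 12.3% in placenta (permutation p = 0.756).

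**Figure D2:**
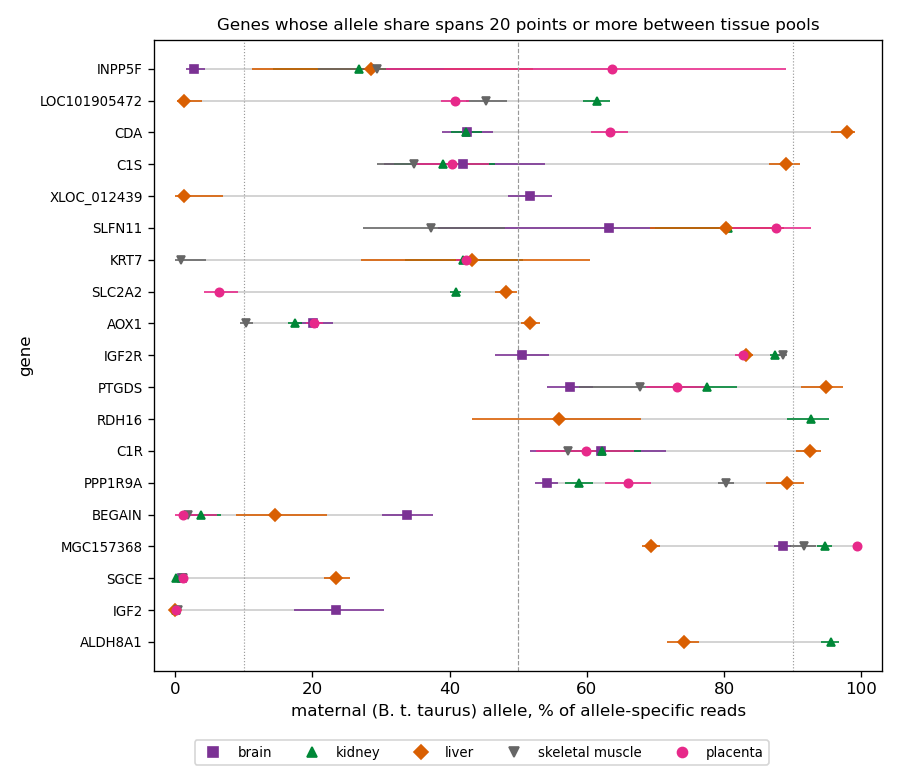
Maternal allele share, as a percent of allele-specific reads (x axis), of the 19 genes whose share spans 20 points or more between tissue pools (y axis). Symbols are tissues, coloured bars are 95% Clopper-Pearson intervals, and dotted lines mark 10% and 90%. Liver lies apart from the other tissues in C1R (92.5%), C1S (89.0%) and CDA (97.8%), and brain in IGF2R (50.6%), IGF2 (23.4%) and BEGAIN (33.8%).

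Several imprinted genes departed in brain. IGF2 had a maternal share of 23.4% [17.3 to 30.5] on 171 reads in brain, against 0.44% or less in the other tissues. IGF2R was read from both alleles in brain, with 50.6% [46.6 to 54.5] maternal reads, against 82.7% in placenta, 83.2% in liver, 87.5% in kidney and 88.5% in skeletal muscle. BEGAIN had 33.8% [30.1 to 37.6] maternal reads in brain, 14.6% in liver and under 4% in the others. INPP5F went the other way, with 2.76% [1.64 to 4.33] maternal reads on 652 reads in brain and 26.8 to 29.4% in kidney, liver and muscle on 21 to 102 reads. In liver SGCE departed, with 23.5% [21.7 to 25.4] maternal reads against 1.19% or less elsewhere. PPP1R9A was spread over the tissues, with 89.1% maternal reads in liver, 80.3% in skeletal muscle, 66.1% in placenta, 58.8% in kidney and 54.1% in brain. Each of these spans passed the permutation test with an adjusted p of 1.55e-05, set by the smallest p the resampling can give, 1e-05.

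Outside the lists, 13 of 26 genes had a span of 20 points or more. C1R and C1S, which lie next to each other, were 92.5% [90.5 to 94.1] and 89.0% [86.5 to 91.1] maternal in liver. In the other tissues C1R was 57.2 to 62.2% and C1S 34.8 to 41.9% maternal. CDA was 97.8% [95.6 to 99.1] maternal in liver, and 42.5 to 63.3% in the other measured tissues. LOC101905472 and XLOC_012439 were read from the paternal allele in liver, with 1.38% and 1.30% maternal reads, and from both alleles in the other tissues where they were measured. AOX1 had 51.8% [50.3 to 53.2] maternal reads in liver and 10.4 to 20.3% in the other tissues. PTGDS was 94.8% maternal in liver and 57.5% in brain, and MGC157368 fell to 69.4% maternal in liver. In muscle KRT7, an epithelial keratin, had 1 maternal among 120 reads, against 42.4% [40.9 to 43.9] in placenta. SLFN11 was 37.4% [27.4 to 48.1] maternal in skeletal muscle and 87.6% in placenta. ALDH8A1, an aldehyde dehydrogenase, and RDH16, a retinol dehydrogenase, were 95.6% and 92.6% maternal in kidney and 74.1% and 55.9% in liver.

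Placenta was then set against each other tissue. Fisher's exact test on reads called 20 of 37 genes against brain, 19 of 43 against kidney, 21 of 38 against liver and 18 of 37 against skeletal muscle (adjusted p under 0.05), of which 6, 3, 10 and 2 differed by 20 points or more. MEG3 is among the genes called against brain and against kidney, both times on the same pair of counts. SLC2A2 was read from the paternal allele in placenta and from both alleles in kidney and liver, and the difference in maternal share was -34.5 points [-36.7 to -31.6] against kidney and -41.8 points [-44.4 to -38.6] against liver. CDKN1C was higher in placenta than in each of the 4 other pools. Its maternal share was 99.7% in placenta and 85.6% [79.5 to 90.5] in brain, and it lay 7.60 points above liver, 5.68 points above muscle and 2.93 points above kidney. PHLDA2 lay 14.4 points [12.6 to 16.5] above kidney, while its 1.59 points over liver did not pass (Fisher's exact adjusted p = 0.166). MEG8 lay 1.90 to 4.10 points above the other tissues. LOC508098 was lower in placenta, with a difference of -6.32 points [-7.82 to -4.87] against liver and -12.7 points [-14.1 to -11.4] against kidney.

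Some listed transcripts had values in 1 tissue only. APCS, serum amyloid P, had 102 of 102 maternal reads in liver, and XLOC_052524 had 368 of 369. In brain, LOC101907203 had 108 of 108 and XLOC_045114 had 51 of 51 paternal reads, and MKRN3, a gene near MAGEL2, had 97.5% [93.7 to 99.3] paternal reads. USP29 and ZIM2, which lie near PEG3, are listed without counts in any tissue, and a footnote of the table says that RT-PCR on randomly primed cDNA detected them.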

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

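All tests in this part were chosen after the values had been seen. Maternal shares that differed between tissue pools in the permutation test on reads were singled out, 38 in number. The span from the lowest to the highest tissue was largest for INPP5F (60.9 points, with 11 placenta reads at its upper end), LOC101905472 (60.1), CDA (55.4), C1S (54.2), XLOC_012439 (50.4) and SLFN11 (50.2). It was 42.4 points for KRT7, 41.8 for SLC2A2, 41.4 for AOX1, 38.0 for IGF2R, 37.3 for PTGDS, 36.7 for RDH16, 35.3 for C1R, 35.0 for PPP1R9A, 32.7 for BEGAIN, 29.9 for MGC157368, 23.4 for SGCE, 23.4 for IGF2 and 21.5 for ALDH8A1. Spans of 5 to 20 points were found for GNASXL (14.8), PHLDA2 (14.4), CDKN1C (14.02), OOEP (13.3), LOC508098 (12.7), RTL1 (6.31), DIRAS3 (6.25) and PEG3 (5.20). Spans under 5 points were found for MEG8 (4.10), NAP1L5 (3.71), MAGEL2 (3.06), LOC100298176 (2.64), LOC101907679 (2.61), GNAS (2.55), H19 (2.16), MEG9 (2.11), PLAGL1 (1.78), MEG3 (1.14) and SNRPN (0.94).

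The first pattern is a set of 11 genes read from a single allele in at least 1 tissue and from both alleles in another: BEGAIN, C1R, CDA, INPP5F, KRT7, PTGDS, RDH16, SLC2A2, MGC157368, LOC101905472 and XLOC_012439. Few reads are argued against, since a single-allele and a both-allele tissue differed in all 11. The test was Fisher's exact test, adjusted over 379 pairs of tissues of all genes. With counts divided by 10, 8 genes kept 10 reads in such a pair, and at least 1 pair still differed in each. For KRT7 and PTGDS this was 1 of 2 pairs. The other 3, INPP5F, RDH16 and XLOC_012439, kept too few reads for that check. For INPP5F the both-allele class rests on 11 placenta reads with an interval of 30.8 to 89.1%. A mapping bias towards the taurus reference that is equal in every tissue would leave the tissues alike. Such a bias is argued against as the whole cause, since 11 of the 11 differed between tissues in the permutation test adjusted over all 48 genes. The genes were picked on a gap in the same reads, so both tests show only that the gap exceeds counting error. Outside the imprinted lists 9 of 26 genes were of this kind and in them 2 of 22 (Fisher's exact test, two-sided, p = 0.045), a call that rests on MGC157368, whose liver share of 69.4% lies near the 70% limit (8 of 26 without it, Fisher's exact p = 0.084). A gene outside the lists may still be imprinted, so this split is not one of imprinted against other genes. A sequence difference between the subspecies that acts in some tissues could account for the genes outside the lists, and it cannot be told apart from tissue-specific imprinting, because every conceptus had an indicus sire and no reciprocal cross was analysed here.

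The second pattern is the share of the repressed allele in placenta among genes read from 1 allele in every tissue measured, of which 9 of 12 paternally read genes had a higher maternal share in placenta than in the other pools together, 4 of them past Fisher's exact test (DIRAS3, SNRPN, LOC101907679 and MAGEL2, the last against no single tissue), while placenta was the highest single tissue in 6. The choice of genes leaves out those with a high share outside placenta. Over the 12 measured genes of the fixed paternal list, 4 were higher and 5 lower past the test against the other pools together. The lower ones were IGF2, SGCE, RTL1, BEGAIN and PEG3. Only PEG3 was lower past the test than each single tissue, with 4.81% maternal reads in placenta and 6.55 to 10.01% in the 4 others. SGCE was lower than liver alone (1.19% against 23.5%) and higher than kidney (0.088%, Fisher's exact adjusted p = 2.68e-06). In single-tissue tests IGF2 did not pass against kidney or liver, BEGAIN against kidney or muscle, and RTL1 against kidney. Of the higher genes, INPP5F passed against brain alone. LOC101907679 had 20 maternal among 728 reads in placenta and 6 among 3316 elsewhere. In all, 8 genes differed between placenta and the other pools by more than counting error. For these genes this argues against misassignment at 1 fixed rate per gene in all pools as the whole cause. Misassignment that differs between positions is not covered, since the counts are not split by position. Moreover, 1 of the 8 genes, SNRPN, rests on a placenta cell whose counts and deposited percent disagree. The list as a whole does not decide on maternal RNA in the placenta libraries, since of its lower genes only PEG3 passed against each tissue. Maternal RNA may account for the genes that were higher. For those genes maternal RNA cannot be told apart from weaker silencing, since 0 of 9 endometrium marker genes are in the table. As it adds maternal reads only, it is argued against for the 3 maternally read genes whose paternal share was higher in placenta, H19 (2.16% against 0.50%), GNAS (2.55% against 0 of 1742 reads) and LOC100298176 (2.67% against 0.12%), while MEG8 went the other way, with 2.56% in placenta and 6.23% elsewhere.

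The third pattern is the even maternal share of PEG10, which spanned 0.63 points over 5 tissues (permutation p = 0.756). Reads assigned to the wrong allele at a fixed set of positions could give such an even share, and so could partial expression of the maternal allele at 1 level in all tissues. The counts are not split by position, so these cannot be told apart. The span of 23.4 points of its neighbour SGCE over the same pools does not decide between them.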

How the results depend on the processing

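Of 94 values of the main results under other settings, 93 stayed within 1.5 times the original count or on the same side of the threshold. The exception was the number of genes that differed between tissues, which was 38 and became 24 with counts divided by 10, all 24 among the 38, where only 35 genes had enough reads left to be tested. That setting, the one without the genes marked for Sanger sequencing, and all settings of the tissue comparisons were chosen after seeing the data. Leaving out each tissue in turn gave 31 to 33 genes. The count of placenta genes with an allele bias was 39 to 42 under the other settings and 31 with counts divided by 10. Genes left with under 10 reads by that division were not tested, so the lower count reflects genes dropped as well as calls lost. A null share of 42.4%, the median of 19 genes outside the lists, gave 39, and since the table holds genes chosen for a bias this median is no estimate of mapping bias. Limits of 80% and 95% gave 34 and 25 placenta genes read from 1 allele, against 30, and 29 and 15 genes with the same allele in every tissue, against 20. The direction against the lists had a Fisher's exact p of 5.95e-06 with only genes past the threshold. None of the 31 genes matched to the reference lies on X, so leaving out X removed no gene. For the 41 named genes, 225 of 229 values kept their call, 0 reversed, and 4 lost it: C1R at 59.8% maternal with counts divided by 2 and 60.0% with counts divided by 10, and C1S at 40.0% with counts divided by 10 and 40.4% under the shifted null. Named genes that fell under the read minimum of a setting are not among the 229. Changing the read minimum or leaving out the Sanger-marked genes left the counts of the remaining genes as they were, so few calls could change there. No paired analysis was possible because the counts are pooled over conceptuses. For the same reason leaving out single conceptuses, the block of conceptus, other count models, other library scalings, the best-covered position per gene and the test of spread between conceptuses were not run. Depth limits INPP5F and DLK1 in placenta most, with 11 and 12 reads.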

Other observations

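The comparisons in this part were chosen after the values had been seen. Neighbouring genes did not always share an allele. In the order of the UOA_Brahman_1 assembly, PPP1R9A, PEG10 and SGCE follow each other with 0 protein-coding genes between neighbours, and PON3 lies 1 gene from PPP1R9A. PON3 was read from the maternal allele with 97.3% of 291 reads in liver, PPP1R9A was 89.1% maternal there, and PEG10 and SGCE were 11.7% and 23.5% maternal in the same pool. In the DLK1 region, BEGAIN, DLK1 and RTL1 were paternal and MEG3, MEG8 and MEG9 maternal in placenta.

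In the class read from both alleles, 33 pairs of gene and tissue had a median maternal share of 51.7%, with 18 above and 15 below 50%.

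The MEG3 counts of brain and kidney are identical. The ratio of MEG3 to MEG8 allele-specific reads was 9.10 in brain and 3.65 in kidney, and it was 3.13, 3.97 and 6.19 in liver, skeletal muscle and placenta. The ratio of MEG9 to MEG8 was 0.0167 in brain and 0.0162 in kidney, and it was 0.0328, 0.0303 and 0.0346 in liver, skeletal muscle and placenta.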
